A study of Mus musculus with 4 samples.

How the data were processed

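RNA of mouse abdominal aorta was measured on 4 one-colour (Cy3) Agilent mouse arrays, each with 62976 spots, of which 59305 were not controls and stood for 56605 probes. The labels give 2 groups of 2 arrays, wild type and SR-A1-/-, both from male mice of 12 weeks, 4 weeks after CaPO4. The labels' numbers differ between groups, so no paired analysis was possible because nothing joins an array of one group to an array of the other. All arrays came from 1 slide and 1 scan time.

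Per the file headers, the processed signal is an intensity made by Agilent Feature Extraction 12.0.3.1, background-subtracted, spatially and multiplicatively detrended, with low values replaced by surrogates, and not normalised between arrays. The notes of the authors name version 10.7 of that program, and limma with no role. The mean spot signal and the median local background are raw intensity values per the file headers, and the other columns used, per the file headers, are flags of 0 or 1. The deposited value table is on a log2 scale, and its 4 columns had almost the same distribution, close to quantile normalisation. Of its 56732 entries 56605 were matched to probes and 127 were not. Probe positions are on mm9.

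The signal was taken as log2 minus the array's 75th percentile over probes that are not controls. Outlier spots were left out (93, 74, 102 and 83 on the arrays labelled wild type replicates 1 and 2 and knockout replicates 1 and 2), 0 spots were saturated, and repeated spots were averaged. Probes well above background on at least 2 of the 4 arrays were kept, which gave 35102 probes, and the brightest probe of each name gave 22497 genes of 37074 names. Of these genes 7970 had several tested probes, and 2902 of those had probes that differed in direction. A fold against a group not above background was computed as a lower bound against the mean over that group of each array's lowest signal called above background. For 6 genes with 1 array of a group under that signal, the difference is also given with that array's value raised to it.

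Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. Values were read and summarised with the R package data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The 41 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, where at least 5 members were tested. Camera with an estimated correlation and fry were run beside it. The comparisons, the lists, the rule for named genes and the alternatives, but for the block named below, were chosen before the data were examined. The named genes were Msr1, up to 12 in each direction by fold change among those past the threshold, filled by smallest p where fewer passed, and the 3 members of each list with the smallest p. The genes filled in had to change at least 2-fold, with both arrays of the higher group above background, a level at or above the median of all tested genes, and an established name.

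Tested on simulated data with 200 changed genes in each of 20 runs, the procedure recovered 0% of genes changed by a log2 of 1, 0.8% at 2, 69.8% at 4 and 97% at 8. A list moved by 1 was called in 20 of 20 runs, with 1 call of another list over all runs. Over those runs 92 unchanged genes were called. Genes were simulated independently of each other, whereas the estimated correlation within called lists reached 0.996, for oxidative phosphorylation. The simulated list calls therefore do not measure how often camera calls a list falsely in these data. The number of arrays limits the precision.

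The alternatives were quantile, median and cyclic loess normalisation, normexp background correction with an offset of 50, no filter or a filter on all 4 arrays, outlier spots kept, the mean of a gene's probes, an intensity trend, robust eBayes, array weights, the deposited values, each array left out, other thresholds, and camera on ranks. Windows of 5 and 20 Mb were set against 10 Mb around Msr1. Signal level as a block was added after the data were seen. No alignment or reference genome was used.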

Results

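Abdominal aortas of male 12-week-old mice were profiled 4 weeks after CaPO4 was used to injure the vessel, in animals labelled wild type and animals labelled SR-A1-/-. SR-A1, encoded by Msr1, is a scavenger receptor of macrophages that takes up modified lipoproteins and other polyanionic ligands. Each of 4 one-colour arrays measured 1 RNA sample, with 2 arrays in each group. The 75th percentile of the processed signal was 132 and 220 on the arrays labelled wild type replicates 1 and 2, and 245 and 133 on the arrays labelled knockout replicates 1 and 2. Between 57.6% and 62.6% of the 56605 probes were well above background, and the number of arrays limits the precision. All differences below are log2 values of the arrays labelled knockout minus those labelled wild type, given ± the limma standard error from 2 arrays per group. The labels do not say whether each array was a separate animal, so the p-values measure only the spread between these samples.

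Msr1, the deleted gene, was read first as a check of the labels, and it went against them. Both of its probes (transcript NM_031195) were well above background on both arrays labelled knockout and on the array labelled wild type replicate 2, and not well above background on the array labelled wild type replicate 1. The probe starting at base 3231 of the transcript, on chromosome 8 at 40689158 to 40689217 (mm9), read -5.30 and -2.10 on the arrays labelled wild type and -1.26 and -2.09 on those labelled knockout, in log2 units relative to the array's 75th percentile. At base 624, at 40709296 to 40709355, the values were -6.40 and -2.12 against -1.50 and -1.38. The difference was 2.03 ± 1.09 at the first probe, which stood for the gene in limma with an adjusted p of 0.965. At the second probe it was 2.82 ± 1.22, in a fit of all probes without missing values, dim ones included. Without the array labelled wild type replicate 1 the first difference was 0.68, and it was 0.53 with normexp background correction. Without the array labelled wild type replicate 2 the only array left in that group was not above background, and the difference from its lowest signal called above background was 2.59. With all 4 arrays and the same lower limit, the difference was 1.5. The allele is not named in the labels, and a probe outside the deleted part would check nothing, so every direction below refers to the labels alone.

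**Figure D1:**
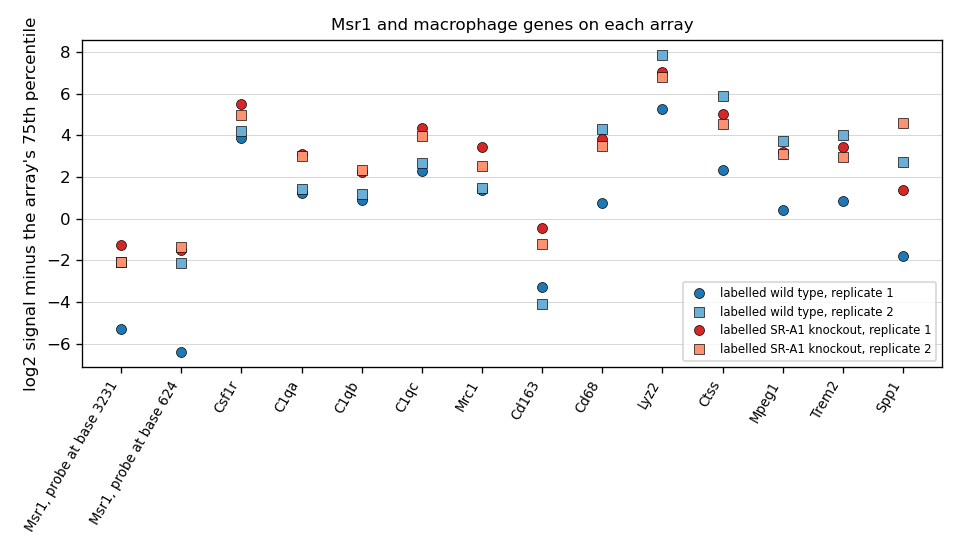
Log2 signal minus the array's 75th percentile (y axis) for both Msr1 probes and 12 macrophage genes chosen after their values were seen (x axis), with 1 point per array, blue for arrays labelled wild type and red for arrays labelled SR-A1 knockout. The array labelled wild type replicate 1 lies lowest for Msr1, Cd68, Ctss, Mpeg1, Trem2 and Spp1, while C1qa is 1.22 and 1.41 on the arrays labelled wild type and at least 3.01 on those labelled knockout.

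The comparison asked which genes differed between injured aortas of both genotypes. Gene lists for antigen presentation, resident-type macrophages and complement were higher on the arrays labelled knockout, with median differences of 1.68, 1.33 and 0.85. Lists for skeletal muscle and contractile smooth muscle were lower, with medians of -1.87 and -0.44, and the clock gene Arntl differed by -3.77 ± 0.66. These calls came from camera at a preset correlation between genes, and with an estimated correlation the lowest adjusted p of any list was 0.534.

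Single genes gave few calls. No gene of the 22497 tested passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.0539. At an unadjusted p under 0.05 there were 1416 genes, 865 higher and 551 lower on the arrays labelled knockout, against 1125 if none had changed. Dividing the 4 arrays by signal level in place of genotype gave 3727 such genes, and the third division gave 277. A difference of at least 2-fold with groups that did not overlap was found in 1439 genes, 891 higher and 548 lower. Groups did not overlap in 29.8% of all genes, against 33.3% by chance. Quantile normalisation called 8 genes, cyclic loess 8, median scaling 7, the values deposited by the authors 8, normexp background correction 22, no filter on dim probes 8, an intensity trend 5 and array weights 2. Leaving out the array labelled wild type replicate 1 or 2 gave 277 and 525 genes, with the lone array assumed to vary like the other group, and leaving out either array labelled knockout gave 0. The count at an unadjusted p under 0.05 was 2194 without the array labelled wild type replicate 1, 889 without knockout replicate 1, with 377 higher and 512 lower, and 756 without knockout replicate 2. The count of 2-fold differences was 2785 without wild type replicate 1 and 2189 without knockout replicate 1, with 1035 higher and 1154 lower.

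By correlation and by median difference, the closest arrays had different labels. Across genes, which are not independent replicates, Pearson's r was highest between wild type replicate 2 and knockout replicate 1, at 0.9704, followed by the arrays labelled knockout at 0.9646 and wild type replicate 1 with knockout replicate 2 at 0.9625. Between the arrays labelled wild type it was 0.9575. The median absolute difference between arrays was 0.277 for wild type replicate 1 and knockout replicate 2 and 0.297 for wild type replicate 2 and knockout replicate 1, against 0.426 within the arrays labelled wild type and 0.385 within those labelled knockout. With signal level as a block, an alternative chosen after the data were seen, limma called 0 genes, and 2814 had an unadjusted p under 0.05.

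Of the genes with the smallest p, none of which passed an adjusted p of 0.05, Mrap2, an accessory protein of melanocortin receptors, had the lowest adjusted p. Its tested probe was not well above background on the arrays labelled wild type. That probe was at least 90.4-fold higher on the arrays labelled knockout (adjusted p = 0.0539), although another Mrap2 probe was above background in the lower group. Mrap2 was called under 8 of the alternatives that kept all arrays. The oxygen-binding protein myoglobin, Mb, was higher by 2.89 ± 0.29, the ribonuclease subunit gene Pop4 by 2.97 ± 0.31 and the eosinophil ribonuclease gene Ear2 by 3.15 ± 0.43. Fgfr1op2, H2-Q5, Apod and Rab6b differed by 2.03 ± 0.28, 2.56 ± 0.37, 1.86 ± 0.27 and 2.03 ± 0.31. Tsc22d4 differed by 2.27 ± 0.28, with 2 of its 4 tested probes higher.

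In the other direction, the mitochondrial carrier gene Slc25a34 differed by -4.11 ± 0.30 (adjusted p = 0.0866) and its neighbour Tmem82 by -3.32 ± 0.30 (adjusted p = 0.121). Cwc22, a splicing factor, differed by -3.05 ± 0.28, and Mcm6, a subunit of the replicative helicase, by -2.65 ± 0.29. Synm, which encodes the muscle intermediate filament protein synemin, differed by -3.49 ± 0.34, with 1 of its 2 tested probes higher on the arrays labelled knockout. Fblim1, a filamin-binding adaptor, differed by -1.85 ± 0.28, Tmem222 by -2.06 ± 0.29, Trnp1 by -2.26 ± 0.37 and Aars2 by -2.37 ± 0.39. Foxs1, Cyp2b10 and Vgll3 differed by -1.87 ± 0.31, -1.73 ± 0.29 and -1.62 ± 0.28. Each of these genes had both arrays of one group above both of the other.

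Antigen presentation genes were called higher on the arrays labelled knockout. The list of MHC class II and dendritic cell markers had a median difference of 1.68, with 9 of 14 measured members higher on both arrays labelled knockout and none lower on both (camera adjusted p = 1.05e-09). Over all genes 0 members passed, and 9 passed when adjusted over the list alone, all higher. Cd74, the invariant chain that escorts class II molecules, was at 3.62 and 3.70 on the arrays labelled wild type and 5.77 and 5.65 on those labelled knockout, a difference of 2.05 ± 0.27 (adjusted p = 0.209). The master regulator of class II transcription, Ciita, differed by 2.02 ± 0.27 and the class II chain gene H2-Ab1 by 2.57 ± 0.40. The call was kept under fry (adjusted p = 0.00329) and was lost with an estimated correlation, at an adjusted p of 0.534. Complement genes were also called higher, with a median of 0.85 and 12 of 16 members higher on both arrays labelled knockout (camera adjusted p = 4e-07, fry adjusted p = 0.00329, and adjusted p = 0.534 with an estimated correlation). The 3 subunit genes of C1q led it, with C1qa at 1.74 ± 0.28, C1qc at 1.66 ± 0.33 and C1qb at 1.25 ± 0.29, and 3 members passed when adjusted over the list alone.

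Resident-type and pan-macrophage lists were called higher on the arrays labelled knockout, and the lipid-associated macrophage list was not called, at a median of 0.21 (camera adjusted p = 0.279). Resident-type macrophage genes had a median of 1.33, with 8 of 12 higher on both arrays labelled knockout and 6 passing when adjusted over the list alone (camera adjusted p = 2.55e-06, adjusted p = 0.534 with an estimated correlation). The haemoglobin scavenger receptor gene Cd163 differed by 2.83 ± 0.45, F13a1 by 1.68 ± 0.37 and the folate receptor gene Folr2 by 2.0 ± 0.50. Pan-macrophage markers had a median of 1.11, with 10 of 20 higher on both arrays and 7 passing when adjusted over the list alone (camera adjusted p = 1.66e-08, adjusted p = 0.59 with an estimated correlation). Without the array labelled wild type replicate 1 the median of this list was 0.35, and without replicate 2 it was 1.70. Between the arrays of low signal level it was 1.62 and between those of high level 0.23. Scavenger receptors other than Msr1 had a median of 0.51 (camera adjusted p = 0.000335, fry adjusted p = 0.0384, and adjusted p = 0.534 with an estimated correlation). They were led by Cd163, the mannose receptor Mrc1 at 1.54 ± 0.40 and Cxcl16 at 0.98 ± 0.28. The list for clearance of dying cells had a median of 0.19 (camera adjusted p = 0.029, fry adjusted p = 0.00609, and adjusted p = 0.534 with an estimated correlation), led by C1qa, Elmo1 and Abca1. This call was lost on ranks and without the array labelled wild type replicate 1, at a median of 0.15, or replicate 2, at 0.19. The median was 0.11 without knockout replicate 1 and 0.29 with quantile normalisation. In the scavenger receptor list and in the clearance list, 1 member each passed when adjusted over the list alone.

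Lists for chemokines, interferon response, T and NK cells and cell division were called higher too. Chemokines had a median of 1.10, with Ccl12 at 2.82 ± 0.34, Cxcl10 at 3.15 ± 0.75 (2.83 with the value under background raised to the lowest signal called above it) and Ccl5 at 2.23 ± 0.60 (camera adjusted p = 4e-07, adjusted p = 0.534 with an estimated correlation). Their median was 0.14 and the call was lost without the array labelled wild type replicate 1, and without replicate 2 it was 2.72. Interferon response genes had a median of 0.75, led by Ifit3 at 2.76 ± 0.51, Cxcl10 and Cxcl9 (camera adjusted p = 4.02e-07, adjusted p = 0.647 with an estimated correlation). This call was lost without the array labelled wild type replicate 1, at a median of 0.35, and the median was 1.21 without replicate 2 and 0.48 with normexp background correction. T and NK cell markers had a median of 0.63 and 9 of 16 members higher on both arrays labelled knockout, with the T cell receptor kinase gene Zap70 at 1.72 ± 0.29 and the cytokine receptor gene Il2rb at 1.29 ± 0.34 (camera adjusted p = 5.87e-06, adjusted p = 0.534 with an estimated correlation). Normexp background correction moved the T and NK median to 0.20 and kept the call. Cell division genes had a median of 0.82, led by Nusap1, Mcm5 and Mki67 (camera adjusted p = 3.43e-06, adjusted p = 0.647 with an estimated correlation). The call was lost without the array labelled wild type replicate 1, at a median of 0.41, and the median was 1.55 without replicate 2 and 0.21 with normexp background correction. Adjusted over the list alone, 1 chemokine gene, 1 T and NK cell marker, 0 interferon response genes and 0 cell division genes passed.

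**Figure D2:**
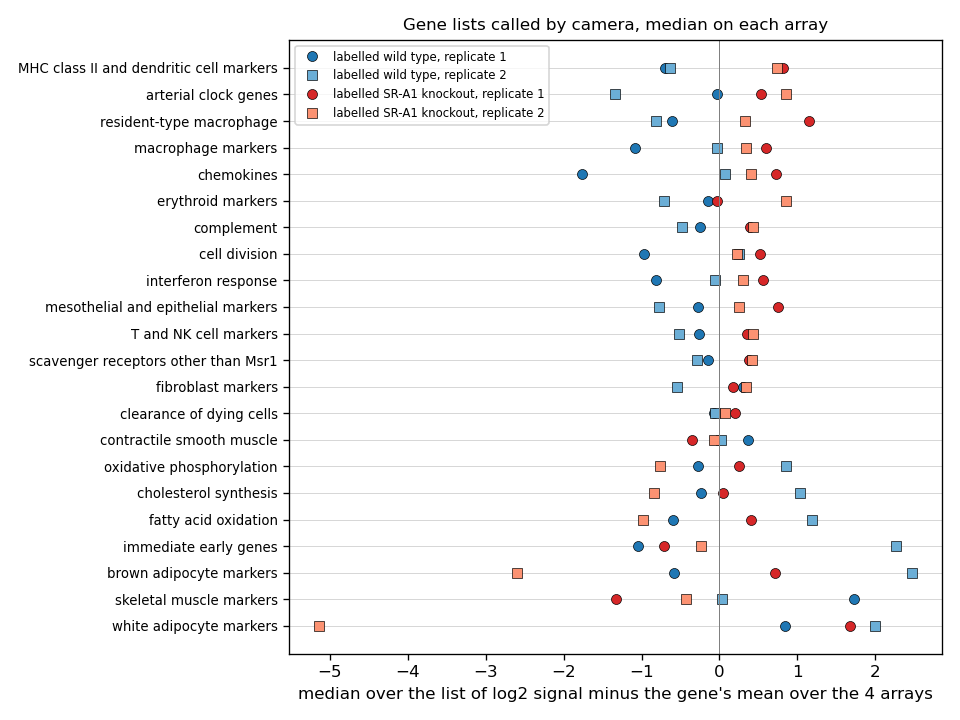
Median over each called gene list of the log2 signal minus the gene's mean over the 4 arrays (x axis), with 1 point per array, blue for arrays labelled wild type and red for arrays labelled SR-A1 knockout. In the MHC class II list both red points (0.81 and 0.74) lie to the right of both blue points (-0.70 and -0.63), whereas white adipocyte markers put the array labelled knockout replicate 2 (-5.14) apart from the other 3.

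Muscle and fat, which surround the aorta, differed between arrays. Skeletal muscle markers had a median of -1.87, with 11 of 16 members lower on both arrays labelled knockout (camera adjusted p = 5.98e-05, adjusted p = 0.774 with an estimated correlation). The fast myosin gene Myh4 differed by -2.28 ± 0.58, while Mb and Myh1, the 2 members that passed when adjusted over the list alone, differed by 2.89 ± 0.29 and 3.63 ± 0.74. The list's median was -0.88 without the array labelled wild type replicate 1. Contractile smooth muscle genes had a median of -0.44 and 12 of 20 lower on both arrays, with Myocd, the coactivator that drives this programme, at -0.93 ± 0.36 and Tpm1 at -1.18 ± 0.47 (camera adjusted p = 8.41e-05, adjusted p = 0.647 with an estimated correlation). Pln, the member with the smallest p, was not well above background on the arrays labelled wild type and at least 1.94-fold higher in the other group. The smooth muscle call was lost without the array labelled wild type replicate 1, at a median of -0.27.

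White adipocyte markers had a median of -3.10 that came from 1 array (camera adjusted p = 0.00554, adjusted p = 0.777 with an estimated correlation). Cfd, the adipocyte protease adipsin, read 7.76 and 8.11 on the arrays labelled wild type, 7.89 on the array labelled knockout replicate 1 and 0.45 on replicate 2. The other members with the smallest p were Lep, at 0.55 ± 0.34, and Acvr1c, at -3.19 ± 2.05, or -2.67 with the value under background raised in the same way as for Msr1. The list's median was 0.35 and the call was lost without the array labelled knockout replicate 2, and without replicate 1 it was -6.69. The median was -1.45 with normexp background correction and -0.99 among genes above background on all 4 arrays. Brown adipocyte markers had a median of -1.30, led by Dio2, Cox7a1 and Cpt1b (camera adjusted p = 0.0131, adjusted p = 0.777 with an estimated correlation). That median was 0.0041 without the array labelled wild type replicate 2 and -0.058 without the array labelled knockout replicate 2, and neither kept the call. It was -3.60 without wild type replicate 1 and -3.14 without knockout replicate 1.

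Metabolic lists were called lower and rested on the same arrays. Oxidative phosphorylation genes had a median of -0.55 (camera adjusted p = 0.000332, adjusted p = 0.777 with an estimated correlation), with Ndufv1, Cox5a and Atp5o at -0.64 ± 0.38, -1.01 ± 0.70 and -0.59 ± 0.44. Fatty acid oxidation genes had a median of -0.65, led by Cpt1b, Hadha and Slc25a20 (camera adjusted p = 0.00554, adjusted p = 0.777 with an estimated correlation). Both calls were lost without the array labelled wild type replicate 2, at medians of -0.066 and 0.20, and without the array labelled knockout replicate 2, at -0.045 and 0.076. Without wild type replicate 1 the medians were -1.10 and -1.45, and without knockout replicate 1 they were -1.01 and -1.30. Cholesterol synthesis genes had a median of -0.64, with Sqle at -1.50 ± 0.53 and Cyp51 at -1.42 ± 0.59 (camera adjusted p = 8.74e-06, adjusted p = 0.774 with an estimated correlation). That call was lost without the array labelled wild type replicate 2, at -0.19, and the median was -0.33 without knockout replicate 2, -1.31 without wild type replicate 1 and -1.16 without knockout replicate 1. Adjusted over the list alone, 0 members of the oxidative phosphorylation, fatty acid oxidation and cholesterol lists passed.

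Immediate early genes had a median of -0.86 (camera adjusted p = 0.0294, adjusted p = 0.777 with an estimated correlation), and Nr4a1 read 8.09 on the array labelled wild type replicate 2 against 5.29, 5.27 and 5.55 on the others. The other leading members were Ier3 at 0.95 ± 0.61 and Ier2 at -1.50 ± 1.01. Without wild type replicate 2 the median was 0.48, and the list was then called higher. Without wild type replicate 1 it was -2.89. The call was lost without knockout replicate 1, at -0.57. It also missed the threshold with median scaling, cyclic loess and array signal level as a block, at medians of -0.91, -0.84 and -0.86 close to that reported (adjusted p = 0.0656, 0.0562 and 0.104).

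Members of the clock list differed in both directions. Arntl, which encodes the activator BMAL1, differed by -3.77 ± 0.66, and Npas2, which can pair with BMAL1, was at least 4.23-fold lower on the arrays labelled knockout, where it was not well above background. Hlf, an output transcription factor of the clock, differed by 2.17 ± 0.39. Of the 15 members 9 were higher and 3 lower on both arrays labelled knockout, with a median of 1.44, and 4 passed when adjusted over the list alone, 2 in each direction (camera adjusted p = 0.00519, adjusted p = 0.534 with an estimated correlation). The output gene Dbp, chosen after its values were seen, read 5.71 and 1.46 on the arrays labelled wild type and 6.76 and 7.15 on those labelled knockout. The list's median was 2.33 without the array labelled wild type replicate 1 and 0.86 without replicate 2. The sample labels give age and weeks after CaPO4 but no hour of collection. Between the groups, a difference in hour thus cannot be told apart from one of genotype. Relative to each gene's mean, the list's medians were -0.035 and -1.34 on the arrays labelled wild type and 0.53 and 0.85 on those labelled knockout. The arrays labelled wild type thus differed from each other too, which their shared label does not account for.

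**Figure D3:**
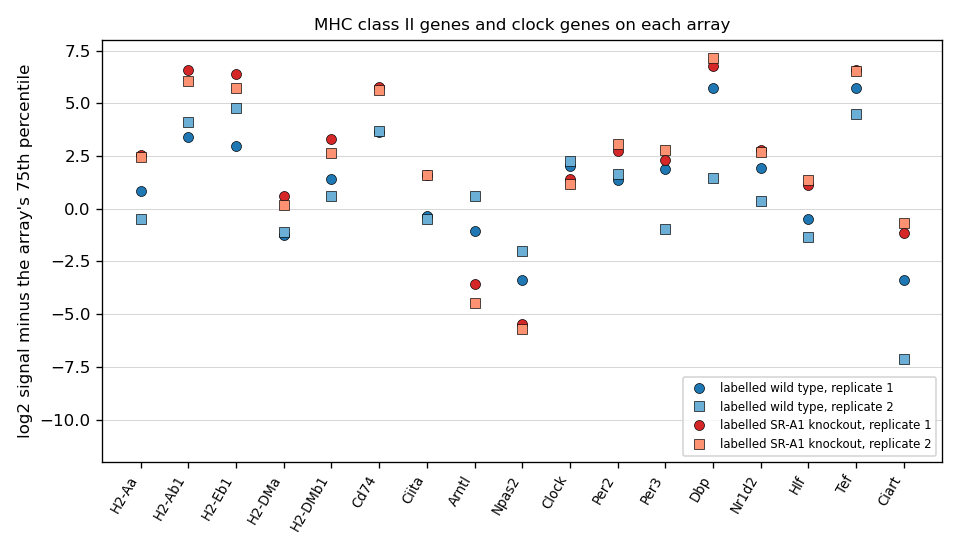
Log2 signal minus the array's 75th percentile (y axis) for 7 MHC class II pathway genes and 10 clock genes chosen after their values were seen (x axis), with 1 point per array, blue for arrays labelled wild type and red for arrays labelled SR-A1 knockout. Ciita is 1.59 and 1.58 on the arrays labelled knockout against -0.37 and -0.50, and Arntl is -3.59 and -4.46 against -1.08 and 0.58.

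Smaller called lists were fibroblast, erythroid and mesothelial markers, all higher. Fibroblast markers had a median of 0.50, led by Lum, Serpinf1 and Smoc2 (camera adjusted p = 0.0162, adjusted p = 0.777 with an estimated correlation), and the median was -0.029 without the array labelled wild type replicate 2 and 0.77 without replicate 1. Without knockout replicate 2 it was 0.40 and not called. Erythroid markers had a median of 0.97, led by Hbb-b1, Hbb-b2 and Hbb-bt (camera adjusted p = 0.00412, adjusted p = 0.772 with an estimated correlation). Without wild type replicate 2 it was 0.63 and without knockout replicate 2 it was 0.48, neither of them called, and with no filter on dim probes it was 0.56. Mesothelial and epithelial markers had a median of 0.74 over 6 measured members, led by Krt8, Krt18 and Msln (camera adjusted p = 0.00286, adjusted p = 0.534 with an estimated correlation). That call was lost without wild type replicate 2, at 0.61, and with normexp background correction, at 0.19. Adjusted over the list alone, 1 erythroid marker, 1 mesothelial marker and 0 fibroblast markers passed.

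Of the 41 lists, 22 were called by camera, 14 higher and 8 lower, and 4 by fry, all higher. Some lists shared members, so their calls are not independent. Cd163 was in the pan-macrophage, resident-type and scavenger receptor lists, and C1qa in the pan-macrophage, complement and clearance lists. Cxcl10 was in the chemokine and interferon response lists. No list was called with an estimated correlation. For the 4 lists called by fry, that correlation was -0.0434 (MHC class II), -0.0647 (complement), -0.0525 (clearance) and -0.0405 (scavenger receptors), all below the preset 0.01. A higher correlation between genes thus does not account for the loss of these 4 calls, and its cause was not tested. Dividing the same 4 arrays in the other 2 ways gave 20 and 12 lists by camera and 0 and 0 by fry.

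Lists for collagens, elastic fibres, matrix proteases and mineralisation were not called by camera. The medians were -0.050 for collagens, -0.059 for elastic fibre genes, where elastin (Eln) differed by -1.35 ± 0.33, and 0.31 for matrix-degrading proteases, where Adamts4 differed by -2.30 ± 0.61. Protease inhibitors had a median of 0.057, TGF-beta targets -0.31, osteochondrogenic genes -0.091, inhibitors of mineralisation 0.063 and osteoclast-type genes 0.27. Among cell types, the medians were 0.21 for lipid-associated macrophages, -0.057 for neutrophils, -0.15 for B and plasma cells, 0.60 for mast cells, 0.044 for endothelium, 0.39 for lymphatic vessels, 0.21 for nerve, 0.17 for exocrine pancreas and 0.53 for kidney and adrenal. Inflammatory cytokines and NF-kB targets had a median of 0.18 and unfolded protein response genes -0.032. The direction of the test differed from the sign of the median for neutrophil, mast cell, osteochondrogenic, osteoclast-type and unfolded protein response genes. For neutrophil, osteochondrogenic and B and plasma cell genes the mean differed in sign from the median. Adjusted over the list alone, 1 B and plasma cell gene passed, Jchain at 2.22 ± 0.37, and 1 mast cell gene, Hdc at -1.61 ± 0.28. Without the array labelled wild type replicate 1 the lipid-associated macrophage list was called at a median of -0.57, and without knockout replicate 1 the osteochondrogenic list was called at 0.61.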

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

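The block by signal level was chosen after the result was seen, and the other alternatives were planned. The count of genes past an adjusted p of 0.05, 0 in the analysis reported, was 8 with quantile normalisation, 7 with median scaling, 8 with cyclic loess, 22 with normexp background correction, 8 with no filter on dim probes, 5 with an intensity trend, 2 with array weights and 8 with the deposited values. It was 17 at an adjusted p under 0.1, and 1080 genes had an unadjusted p under 0.05 and a 2-fold difference. Leaving out 1 array gave 0 to 525 genes, with the lone array assumed to vary like the other group. The count stayed 0 with a filter on all 4 arrays, outlier spots kept, the mean of probes, robust eBayes and the block by signal level. Genes with an unadjusted p under 0.05, 1416 as reported, were 924 with normexp, 467 higher and 457 lower, and 2814 with the block, 1424 higher and 1390 lower. Median scaling gave 720 higher and 647 lower. Leaving out 1 array gave 756 to 2194. Genes with a 2-fold difference, 1439 as reported, were 409 with normexp, 2314 with no filter, 911 with a filter on all 4 arrays and 1806 to 2785 with 1 array left out. The all-array filter tests fewer genes and leaving out an array removes samples, and for the other shifts the cause was not tested.

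Msr1 kept its direction, at 0.68 to 3.63 with 1 array left out and 0.53 with normexp. The value of 3.63 is against a single array that was not above background, and against that array's lowest signal called above background it was 2.59. Msr1 was not tested under the filter on all 4 arrays, which it does not pass. The 22 called lists were 0 with an estimated correlation, 4 with fry and 18 to 24 under the other alternatives. The share of genes near Msr1 with an unadjusted p under 0.05, 3.73% as reported, was 0 in the 5 Mb window and 4.13% in the 20 Mb window. A block by slide or scan date was not run, because there was 1 of each. Genes at or near background limit the fold changes, which for named genes were given as lower bounds where both arrays of a group were not above background.

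Some values changed sign, and the cause was not tested. With quantile normalisation the medians were 0.045 for collagens, 0.056 for elastic fibre genes and 0.010 for neutrophil markers, and with the deposited values they were 0.0035 for elastic fibre genes and 0.0032 for neutrophil markers. Endothelial markers were at -0.0080 with median scaling. Normexp gave -0.010 for Msln and -0.0069 for exocrine pancreas markers. Kidney and adrenal markers were at -0.083 with no filter, and the unfolded protein response was at 0.0010 with the mean of probes.

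With each array left out in turn, some values had both signs, and part of the change is the smaller number of arrays. Nr4a1 ranged from -2.68 to 0.11. The medians ranged from -0.26 to 0.12 for collagens, -0.26 to 0.089 for elastic fibre genes, -0.57 to 0.73 for lipid-associated macrophages and -0.032 to 0.61 for osteoclast-type genes. They ranged from -0.029 to 0.77 for fibroblast, -0.13 to 0.12 for neutrophil, -0.063 to 0.30 for endothelial, -0.11 to 0.96 for lymphatic and -0.37 to 1.32 for mast cell markers. White adipocyte markers ranged from -6.69 to 0.35, brown adipocyte from -3.60 to 0.0041, exocrine pancreas from -0.0041 to 0.43 and kidney and adrenal from -0.072 to 0.81. The range was -0.47 to 0.61 for osteochondrogenic genes, -0.039 to 0.44 for inhibitors of mineralisation, -0.20 to 0.49 for the unfolded protein response and -0.033 to 0.59 for NF-kB targets. It was -2.89 to 0.48 for immediate early genes, -1.45 to 0.20 for fatty acid oxidation and -0.46 to 0.13 for TGF-beta targets. Over all alternatives, named genes kept their direction and side of the threshold in 1265 cases, passed it in 76 and changed sign in 2. Lists did so in 696 cases, lost their call in 60, gained one in 25 and changed sign in 36.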

Other observations

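All tests below except that of the genes near Msr1 were chosen only after the result was seen. Immunoglobulin genes, a group picked after their values were seen, were higher on the arrays labelled knockout. Of 68 tested, 49 were higher on both of those arrays and 3 lower on both, with a median difference of 1.80 (camera p = 1.038e-32, p = 0.0326 with an estimated correlation, fry p = 0.0244). The constant regions of gamma 2B and gamma 2C, parts of IgG antibodies, differed by at least 4.31 and 4.06, with 1 array labelled wild type not above background raised to its lowest signal called above it. Kappa differed by 1.93 ± 0.38 and alpha by 1.82 ± 0.43. The probes for mu were at 1.24 ± 0.47 and 0.42 ± 0.42, those for delta at -0.10 ± 0.44 and 0.35 ± 0.57, and 1 probe for lambda at 0.63 ± 0.52, while another was above background on 1 array of each group. Jchain, which joins secreted IgA and IgM, differed by 2.22 ± 0.37. The B cell surface gene Ms4a1 was at -0.90 ± 0.42, and the plasma cell gene Mzb1 at 0.057 ± 0.32.

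The array labelled wild type replicate 1 had low values of a set of macrophage genes, also named after their values were seen. Against replicate 2, Dcstamp, a fusion protein of osteoclasts and giant cells, was not above background, with a log2 difference of at most -4.11 against its lowest signal called above background. The matrix protein gene Spp1 differed by -4.54, Cd68 by -3.53, Mpeg1 by -3.29 and the lipid receptor gene Trem2 by -3.16. Csf1r, C1qa and Mrc1 differed between these arrays by -0.33, -0.19 and -0.086, and Folr2 and Cd163 by 0.66 and 0.83. Genes at least 8-fold below all other arrays numbered 38 on this array, 13 on wild type replicate 2, 1 on knockout replicate 1 and 57 on knockout replicate 2.

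Msr1 was at background on the array labelled wild type replicate 1 and above background on the other 3. The macrophage markers had a median of -0.8173 between the arrays labelled wild type (95% bootstrap interval -1.70 to -0.26). That interval lay above the bound of -2.14 for Msr1, from its probe at base 624. Members ranged from -3.57 for Ctss to 0.87 for Itgam, so the markers did not fall evenly. An even loss of macrophages of every kind was thus argued against for these arrays, but the median cannot decide on an uneven loss. Fewer lipid-associated macrophages in that sample may account for the low Msr1 and stay open. Their median was -1.575 (-2.27 to -0.58), which does not exclude the bound. Both intervals resample the genes of a list from 1 array against 1, which measures no spread between samples. A single wrong label would leave at most 1 array labelled knockout with both Msr1 probes above background, and there were 2. If the probes lie in the deleted part, this argues against a single wrong label alone. The 2 arrays are part of the pattern itself and the allele is not named, so wrong labels in general stay open.

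MHC class II and dendritic cell genes were higher on the arrays labelled knockout. Endothelial markers lay 1.638 below the list's median (95% bootstrap interval 0.65 to 2.10). This cannot decide on a lower share of fat and muscle, since those tissues hold endothelium too and would lose it with them. Without knockout replicate 2 the white adipocyte median was 0.35 while that of the class II list was 1.61, and the skeletal muscle median was -2.21. Within each signal level, which held 1 array of each label, the class II list had a positive median. That median was 1.506 (0.96 to 2.03) in the low and 1.63 (0.19 to 2.09) in the high, from 1 array against 1. With 9 of 14 members higher on both arrays labelled knockout, its sign was fixed by the pattern itself. It thus cannot decide on the signal level. Intervals in this paragraph resample the genes of a list, which are not independent replicates, and measure no spread between samples. The 4 arrays make 3 splits into pairs, too few for a share under 0.05, and 1 split, the real one, called as many as 22 lists, with 20 the highest other. An effect of the genotype on antigen presentation remains a hypothesis that may hold, along with differences between individual samples, since both stay untested.

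Genes with a small p lay near each other on several chromosomes, such as Fblim1 at -1.85, Tmem82 at -3.32 and Slc25a34 at -4.11, all on chromosome 4. DNA of another strain around Msr1, where 3.731% of 134 genes within 10 Mb had an unadjusted p under 0.05 (95% exact interval 1.22 to 8.49) against 6.29% of other genes, was left open by too few genes (Fisher's exact p = 0.283, two-sided). Within 5 Mb the count was 0 of 54, which goes against it (p = 0.0487, not adjusted over the 3 windows), but the exact interval reached 6.6%, above the 6.29% of other genes. Among the 200 named genes with the smallest p there were 50 pairs within 1 Mb, against a median of 33 and a 95th percentile of 46 in 1000 random sets, and 25 and 40 in the other splits of the arrays, and in 20 of the 50 the genes differed in opposite directions. A strain difference at other places in the genome may account for such pairs and cannot be told apart from shared regulation of neighbours, since both give pairs.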
